A study of Mus musculus with 6 samples.

How the data were processed

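Microglia were enriched from cortex and hippocampus of 6 mouse samples aged 9.5 months. Tissue was dissociated with accutase, myelin was removed and CD11b-bearing cells were selected, CD11b being a surface protein of microglia and other myeloid cells. Each sample gave 1 droplet-based single-cell RNA library. The labels name 3 genotypes, P301S;ATTAC, P301S and C57BL/6;ATTAC, with 1 female and 1 male library each. P301S is a transgene for mutant human tau. INK-ATTAC is a transgene that places an inducible caspase under the promoter of p16, a product of Cdkn2a. The labels name no treatment and do not say whether a library holds 1 mouse or a pool. Replicate numbers follow the order of the samples in the series and pair nothing. Replicate 1 of each group is female and replicate 2 is male.

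The values deposited by the authors are raw UMI counts per gene and cell barcode, without normalization. The deposited barcode lists hold one barcode per called droplet, and the deposited gene lists give the symbol and identifier of each of 31055 features, the same in every library. Per the labels, Cell Ranger 3.0.2 aligned the reads to mm10. The feature list also holds hMAPTP301S and INKATTAC, the transgene sequences. The annotation release used by the authors is not stated. Gene positions given here come from GENCODE vM21 on GRCm38 and were matched by Ensembl identifier.

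Cells with at least 500 genes and at most 10% mitochondrial UMIs were used. Scrublet, run per library in scanpy 1.11.5, called fewer than 0.5% of cells, so the top 3% of its scores in each library were left out, a rule set once the calls were seen. Counts were clustered on 2000 variable genes (without the transgenes, Tsix and the genes used to check labels, Xist and the Y-linked ones among them), 30 principal components and 15 nearest neighbours, with Leiden resolution 0.5 (leidenalg 0.10.2) and no integration of libraries. Clusters were named from marker lists of microglia, border-associated macrophages, monocytes, dendritic cells, neutrophils, T cells, NK cells, B cells, neurons, oligodendrocytes, astrocytes, endothelial cells, mural cells, choroid plexus or ependymal cells and erythroid cells. A cluster stayed unnamed when its median depth was low, when cell-cycle genes or markers of several classes led it, or when too few markers of its best class were among its top genes. The exact naming thresholds were set after the clusters were seen.

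For each library, UMIs were summed over microglia-like cells. Genes were tested with edgeR 4.0.16 (filterByExpr, TMM factors, quasi-likelihood F-test) on all 6 libraries with genotype and sex in the model, which leaves 2 residual degrees of freedom and an estimated 16.2 prior degrees of freedom. The interaction of P301S and sex was fitted with the 2 P301S groups pooled (9.72 prior degrees of freedom). P values were adjusted by Benjamini-Hochberg over all genes tested, and an adjusted p under 0.05 made a call. Errors beside log2 differences are standard errors of this fit. Normalised CPM values use the TMM library sizes. Genes with 0 UMIs in a group are given as at least N-fold against a floor of 3 UMIs over that group, and genes with 1 to 3 UMIs as a ratio with its exact 95% counting interval.

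The 17 gene lists were homeostatic microglia, disease-associated microglia (27 of 28 genes were used), type I interferon response, MHC class II, MHC class I, chemokines and NF-kB response, senescence, senescence-associated secretory phenotype, cell cycle, lysosome, lipid handling, cholesterol synthesis, complement, glycolysis (12 of 13 genes were used), nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, and immediate-early and heat-shock genes. Each was tested with camera in limma 3.58.1 at the preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison. Camera with an estimated correlation and fry were run beside it. The lists, the cell filters, the comparisons, the tests and the rule for named genes were fixed before the data were examined. The rule names, per comparison, up to 12 rising and 12 falling called genes with the smallest p whose difference has the same sign in both sexes (for sex, in all 3 genotypes, and for Cdkn2a status, in every library used), without predicted genes. It adds a fixed panel of microglial genes and up to 4 members with the smallest p of each list described.

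Shares of cell classes and per-cell list percentages were compared by exact two-sided permutation tests over libraries. With 2 libraries against 2 the smallest possible p is 0.333, with 4 against 2 it is 0.0667, and with 3 against 3 it is 0.1. These tests take no account of sex. For per-cell values, cells were thinned to 1500 UMIs and shallower cells were left out. Cells with and without a Cdkn2a UMI were to be compared within libraries that had at least 5 positive cells, by an exact two-sided sign-flip test. Thinned, only 1 library met that minimum, so the values without thinning, also planned beforehand, are given. The comparison of genes between cells with and without a Cdkn2a UMI was likewise made without thinning, in edgeR with library as a block. It was repeated on 20 random draws of cells, each drawn from the 25 cells nearest in UMIs to each positive cell.

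Alternatives planned were DESeq2 1.42.0 (Wald test), its size factors in edgeR, no filter on low counts, no covariate, the compared groups alone, all cells, at least 200 genes with at most 20% mitochondrial UMIs, doublets kept, Leiden resolution 1, libraries thinned to the smallest, no clusters led by disease-associated genes, thinning to 1000 UMIs, the per-cell list without 5 abundant members, and each library left out in turn. Added after the data were seen were cluster 0 alone, the low-UMI clusters added to the microglia-like cells, droplets under 3000 CPM of Malat1 left out, and negative cells nearest in depth to the positive ones. The fit of the compared groups alone also left out sex. A cluster counted as led by disease-associated genes when at least 3 of them were among its top 10 genes. Leaving out a library was not planned for class shares and per-cell list values. For gene lists, all cells, no disease-associated clusters and libraries thinned to the smallest were not planned either. The gene fits were tested on simulated data with 100 genes changed at each size. At a log2 change of 1, edgeR recovered 71 to 84% of them in the 5 comparisons of groups, 30% in the interaction and 56% in the comparison by Cdkn2a UMI. Unchanged genes made up 3.40 to 9.32% of calls, in counts simulated from the fitted spreads. The 3.40% belongs to the comparison by Cdkn2a UMI. There, random draws of real cells gave 5 to 32 calls beside 113 in the actual comparison. Of 100 unchanged lists per comparison, at most 4 had an unadjusted camera p under 0.05. A simulated changed list had p values of 0.00357 to 0.0308 with an estimated correlation. Simulated genes were drawn independently of one another. The list simulations therefore do not show how either camera setting behaves on lists whose genes vary together.

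Exact binomial (Clopper-Pearson) 95% intervals accompany shares of cells, and a count of 0 is given with the share that 3 cells would make. These intervals cover counting error only. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and R 4.3.3, and figures matplotlib 3.10.9.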

Results

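Single-cell transcriptomes of CD11b-selected cells from mouse cortex and hippocampus were measured in 6 libraries, 2 for each of 3 genotypes. P301S mice express mutant human tau. They were represented with the INK-ATTAC transgene (group P301S;ATTAC, called P301S mice with ATTAC here) and without it (group P301S, called P301S mice without ATTAC). C57BL/6 mice labelled ATTAC were the controls. Each genotype had 1 female and 1 male library, in that order in every series of 6 values that follows. The libraries held 3916, 4189, 4628, 7104, 3069 and 4413 barcodes and 17236719, 28837285, 24890782, 40434574, 16381569 and 27041934 UMIs. After filtering, 745, 1811, 1461, 2963, 644 and 1787 cells were clustered, with median depths of 5679, 8036, 6857, 6608, 7424 and 6743 UMIs per cell. The mitochondrial limit removed 2310, 1480, 1923, 2581, 1721 and 1937 barcodes, the gene minimum 838, 842, 1199, 1468, 684 and 634.

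The transgene and sex-linked transcripts were counted over all barcodes as a check of the labels. Human tau transcript (hMAPTP301S) gave 407, 364, 539 and 379 UMIs in the 4 P301S libraries, 23.6, 12.6, 21.7 and 9.37 CPM. The female control library had 0, which allows up to 0.183 CPM, and the male control library had 2, or 0.0740 CPM. Xist, the RNA that silences an X chromosome (ENSMUSG00000086503, chromosome X, 103460366 to 103483254, minus strand), gave 9807, 19492 and 10305 UMIs in the female libraries and 2, 6 and 4 in the male ones. Ddx3y on the Y chromosome gave 0 UMIs in each female library and 1580, 1885 and 1505 in the male ones, and Eif2s3y 0 in each female library and 1402, 1881 and 1382. Kdm5d gave 1, 6 and 5 UMIs in female and 574, 664 and 499 in male libraries, and Uty 0 in each female library and 770, 815 and 722 in the male ones. INKATTAC was nearly undetected. The libraries labelled P301S;ATTAC had 0 UMIs each, which allows up to 0.174 and 0.104 CPM, while the libraries labelled P301S had 5 and 2 (0.201 and 0.0495 CPM) and the control libraries 3 and 4 (0.183 and 0.148 CPM). The ATTAC labels therefore have no support from this transcript, and each direction drawn from ATTAC below is stated by label. Mouse Mapt stood at 75.4, 30.9, 52.9, 35.2, 69.2 and 41.1 CPM, Prnp at 340, 134, 188, 151, 238 and 173, and Casp8 at 44.7, 81.7, 61.4, 66.3, 53.2 and 82.4.

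Microglia-like cells made up 45.8, 59.5, 54.6, 61.3, 50 and 48.1% of clustered cells, a total of 341, 1077, 797, 1816, 322 and 860 cells with 3396739, 14436327, 8890317, 19627716, 3584140 and 8740109 UMIs. They fell into 4 clusters. Cluster 0 (2206 cells) was led by the homeostatic genes P2ry12 and Tmem119, cluster 2 (1369 cells) by Cd83, Lag3 and Cd9, cluster 3 (1316 cells) by Spp1, Ccl4, Ccl3, Mmp12 and Lpl, and cluster 7 (322 cells) by the interferon-induced Cxcl10 and Ifit3. Cluster 0 held 45.3 and 44.5% of cells in the control libraries and 31.7, 17.4, 22.4 and 8.10% in the P301S libraries. Cluster 3 held 0.776 and 0.448% in the control libraries and 4.97, 19.4, 12.7 and 24.6% in the P301S libraries, and cluster 2 held 3.11 and 1.62% against 6.17, 18.9, 13.1 and 24.97%. These cluster shares are described and not tested, because the genes that define the clusters are among those compared below.

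Unnamed clusters held 47.9, 32.0, 37.9, 31.9, 39.9 and 42.3% of cells. The largest, cluster 1, had a median of 2006 UMIs per cell and was led by AY036118, Crybb1, Aif1, Cst3 and Lars2, and it held 23.6, 21.3, 25.6, 19.2, 27.2 and 20.1% of cells. Cluster 4, also of low depth, held 7.65, 4.14, 3.83, 5.13, 2.17 and 12.9%. Clusters 1 and 4 each had 16 of 16 microglial markers detected in at least 20% of their cells and stayed unnamed for low depth. With 200 genes and 20% mitochondrial UMIs as limits, low-depth clusters were also named microglia-like. Microglia-like cells then made up 67.3, 77.1, 75.6, 79.3, 67.3 and 73.4% of cells. Cluster 8 mixed astrocyte and neuron genes (Slc1a2, Aldoc, Camk2a).

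Named classes other than microglia-like cells were small. T cell-like cells numbered 0, 10, 8, 13, 0 and 1. Counts of 0 allow shares of up to 0.403% in the female P301S mice with ATTAC and 0.466% in the female controls. Their mean share was 0.385% in the 4 P301S libraries and 0.0280% in the 2 control libraries, a difference that the exact permutation test did not separate from the spread (p = 0.267). Astrocyte-like cells averaged 1.61% in P301S and 3.44% in control libraries (exact p = 0.133). Within each sex both P301S libraries had fewer, 2.95 and 1.44% against 4.19% in females and 1.33 and 0.742% against 2.69% in males. With 200 genes and 20% mitochondrial UMIs as limits, the exact permutation p for astrocyte-like cells was 0.0667. Border-associated macrophage-like cells averaged 3.32 and 3.995% (exact p = 0.533), choroid plexus or ependymal cell-like cells 1.37 and 1.95% (exact p = 0.467), and neutrophil-like cells 0.628 and 0.420% (exact p = 0.467). The border-associated macrophage-like cluster was mixed. H2-Eb1, H2-Aa, H2-Ab1, Cd74, Mgl2 and Cd209a led it beside the macrophage markers Mrc1, Pf4 and F13a1. At Leiden resolution 1, 187 cells carried the name (means of 1.88 and 2.48%, exact p = 0.2), and a cluster of 176 cells led by H2-Eb1, H2-Aa, H2-Ab1 and Ccr2 stayed unnamed. These tests ignore sex. Within females the 2 P301S libraries had 0.134 and 0.205% neutrophil-like cells against 0 of 644 in the control (up to 0.466%), and within males 1.16 and 1.01% against 0.839%. For border-associated macrophage-like cells the values were 2.28 and 3.42% against 4.97% in females and 3.75 and 3.81% against 3.02% in males. With 200 genes and 20% mitochondrial UMIs as limits, 295 cells carried that name (means of 2.00 and 2.51%, exact permutation p = 0.0667). Their shares were 2.03 and 1.77% against 2.81% in females and 2.03 and 2.17% against 2.21% in males. For choroid plexus or ependymal cell-like cells, under the main limits, the shares were 0.940 and 1.98% against 0.932% in females and 1.71 and 0.844% against 2.97% in males. Microglia-like cells averaged 55.3 and 49.1% (exact p = 0.333). The smallest p this design allows is 0.0667.

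Among the UMIs of microglia-like cells, microglial markers held 4.46 to 5.72% over the 6 libraries. Markers of astrocytes held 0.0328 to 0.0468%, of B cells 0.0217 to 0.0335%, of border-associated macrophages 0.0187 to 0.0261%, of choroid plexus or ependymal cells 0.00695 to 0.0249%, of oligodendrocytes 0.00870 to 0.0105% and of T cells 0.00245 to 0.0101%. Markers of neutrophils held 0.000562 to 0.00718%, of neurons 0.00168 to 0.00371%, of endothelial cells 0.00192 to 0.00319%, of monocytes 0.000509 to 0.00137%, of dendritic cells 0.000547 to 0.000892%, of NK cells 4.58e-05 to 0.000331%, of mural cells 6.93e-05 to 0.000206% and of erythroid cells 1.14e-05 to 0.00100%.

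Droplets with little Malat1, an RNA kept in the nucleus, differed between genotypes. Under 3000 CPM of Malat1, a limit chosen after its distribution was seen, lay 40, 279, 175, 520, 9 and 12 microglia-like droplets, or 11.7, 25.9, 22.0, 28.6, 2.80 and 1.40%. The mean was 22.1% in P301S libraries and 2.10% in control libraries, a difference of 19.96 points (exact permutation p = 0.0667, the smallest possible). Within the microglia-like class, these droplets carried more disease-associated and less homeostatic RNA. In the 4 P301S libraries Spp1 stood at 18.95, 4.69, 3.99 and 2.14 times its CPM in the other microglia-like droplets of the same library, Lgals3 at 28.2, 4.88, 5.24 and 4.27, Cst7 at 8.77, 2.93, 4.76 and 2.41, Apoe at 4.35, 1.54, 2.26 and 1.36 and P2ry12 at 0.117, 0.257, 0.136 and 0.226. In the controls, with 9 and 12 such droplets, Apoe stood at 0.815 and 5.198 and P2ry12 at 0.377 and 0.217. Without thinning, the disease-associated list took a median of 6.71, 7.04, 7.03 and 8.92% of their UMIs in the P301S libraries, against 2.22, 3.67, 2.81 and 5.14% in the other droplets. In cluster 3, 75.7, 68.4, 71.0 and 66.1% of droplets of the P301S libraries lay under the limit (3 of 5 and 4 of 8 droplets in controls, at most 0.949% in cluster 0 of any library, and 93.2 to 96.8% in the unnamed cluster 1 of every library), with median depths of 2381 to 3394.5 UMIs against 14879 to 20537 in the rest. Of the low-Malat1 microglia-like droplets, 28, 240, 132, 482, 3 and 4 lay in cluster 3, which Spp1, Lgals3 and Cst7 help lead. Cluster 1, left out of the class for low depth, held 168, 372, 362, 531, 169 and 343 low-Malat1 droplets. The RNA contrast is thus not independent of how clusters were drawn and kept. With the low-UMI clusters added, the difference between genotypes was 11.3 points. Within the class the share moved with the P301S groups, so the comparisons below also give values without the low-Malat1 droplets.

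**Figure D1:**
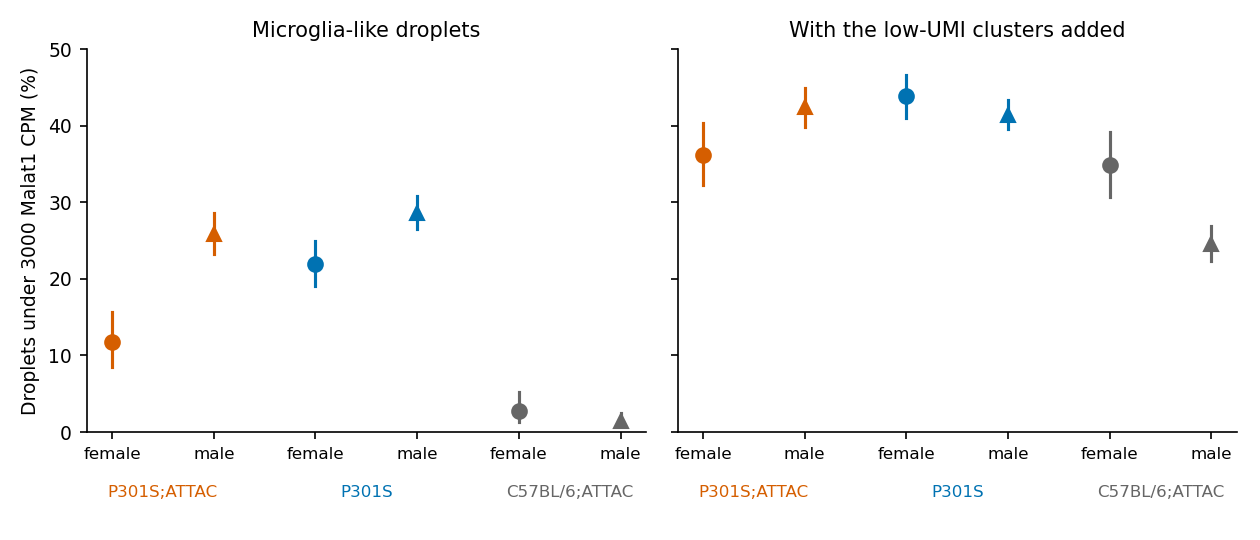
Percent of droplets under 3000 CPM of Malat1 in each library, among microglia-like droplets (left) and with the low-UMI clusters added (right), with exact 95% intervals. The 4 P301S libraries lie between 11.7 and 28.6% on the left and the controls at 2.80 and 1.40%, and on the right all lie between 24.6 and 43.8%.

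The labels of P301S mice with ATTAC and of control mice differ by P301S alone, so this comparison asks what mutant tau changes in microglia. Disease-associated genes rose steeply in microglia-like cells of P301S mice (n = 2 libraries per group). Apoe, the lipid carrier (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188, minus strand), stood at 5521 and 22824 CPM against 2178 and 1412 in controls, a log2 difference of 2.58 ± 0.51 (adjusted p = 0.00517). Cst7, an inhibitor of lysosomal proteases (ENSMUSG00000068129, chromosome 2, 150570415 to 150578944, plus strand), stood at 67.4 and 349 CPM against 7.47 and 19.4 (3.83 ± 0.25, adjusted p = 1.71e-08). Lipoprotein lipase (Lpl) rose by 3.97 ± 0.28, the galectin gene Lgals3 by 4.63 ± 0.31 and the integrin Itgax by 4.07 ± 0.37. Spp1, which encodes osteopontin, had 306 and 7246 UMIs against 1 and 2, a ratio of 2001 (95% counting interval 684 to 9706).

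In this comparison 22 of 27 disease-associated genes rose and none fell (26 and 0 adjusted over the list alone), with a median log2 difference of 2.05. The preset camera test called the list, with adjusted p = 0.118 with an estimated correlation. In the MHC class II list 6 of 7 genes were higher (7 adjusted over the list alone, median 4.08, adjusted p = 0.106 with an estimated correlation), led by Cd74 at 4.16 ± 0.24 (adjusted p = 9.38e-09) and H2-Aa at 4.57 ± 0.30. Without the disease-associated clusters the list's median was 0.91 and in cluster 0 alone 0.66. Per cell and without thinning, the list took a median of 0.0212 and 0.0426% of UMIs against 0.0169 and 0.0213% in controls, and a mean of 0.0769 and 0.130% against 0.0204 and 0.0278%, so the median cell rose less than the mean. In the MHC class I list 3 of 12 were higher (8 adjusted over the list alone, median 0.51, adjusted p = 0.118 with an estimated correlation), led by H2-D1 at 1.27 ± 0.20. Of the interferon-response genes, 19 of 24 rose (21 adjusted over the list alone, median 1.08, adjusted p = 0.118 with an estimated correlation), among them Ifitm3 by 2.25 ± 0.19 and Ifit3 by 1.07 ± 0.17. Of the chemokine and NF-kB genes, 11 of 17 rose (11 adjusted over the list alone, median 1.27, adjusted p = 0.106 with an estimated correlation). They included Il1b by 2.48 ± 0.31, Ccl3 by 2.64 ± 0.34 and Il1rn, with 2 control UMIs and a ratio of 62.8 (counting interval 17.1 to 523).

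Other lists passed the preset test with a part of their genes called, and none passed with an estimated correlation. Of the lipid-handling genes, 9 of 16 rose (12 adjusted over the list alone, median 1.21, adjusted p = 0.118 with an estimated correlation), such as the fatty-acid binding gene Fabp5 by 3.30 ± 0.27. Of the secretory phenotype genes, 13 of 26 rose and 1 fell (14 and 1 adjusted over the list alone, median 0.71, adjusted p = 0.118 with an estimated correlation), including the protease Mmp12 by 4.46 ± 0.49. Of the glycolysis genes, 8 of 12 rose (9 adjusted over the list alone, median 0.71, adjusted p = 0.215 with an estimated correlation). Of the lysosome genes, 3 of 24 rose (11 adjusted over the list alone, median 0.45, adjusted p = 0.275 with an estimated correlation). Of the oxidative phosphorylation genes, 3 of 18 rose (14 adjusted over the list alone, median 0.44, adjusted p = 0.293 with an estimated correlation). Of the complement genes, 2 of 10 rose (2 adjusted over the list alone, median 0.44, adjusted p = 0.215 with an estimated correlation), C3 by 4.15 ± 0.57 and C4b by 1.75 ± 0.32. Of the cell-cycle genes, 3 of 13 rose (8 adjusted over the list alone, median 0.43, adjusted p = 0.118 with an estimated correlation). Of the senescence genes, 3 of 15 rose (4 adjusted over the list alone, median 0.15, adjusted p = 0.196 with an estimated correlation). They were Plaur by 1.64 ± 0.24, Glb1 by 0.96 ± 0.17 and the cell-cycle inhibitor Cdkn1a by 0.96 ± 0.20, while Cdkn2a had 3 and 34 UMIs against 1 and 7 (1.75 ± 0.62, adjusted p = 0.124).

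Fewer genes fell. The cAMP-regulated Arrdc3 fell by 0.88 ± 0.18, the transcription factor Ets1 by 1.20 ± 0.26 and the circadian repressor Nr1d2 by 0.79 on the log2 scale. Gnb4 was called lower only through the female libraries, at 0.576 and 0.0728 CPM against 19.7 and 0.207 (34.0-fold, counting interval 11.2 to 168, from 3 UMIs). No homeostatic gene was called over all genes (0 higher and 2 lower adjusted over the list alone, of 18, median -0.30, preset adjusted p = 0.000216, adjusted p = 0.299 with an estimated correlation). P2ry12, the ADP receptor of resting microglia, was at -0.59 ± 0.25 (adjusted p = 0.229), Tmem119 at -0.43 (adjusted p = 0.303), Cx3cr1 at -0.42 (adjusted p = 0.476), Trem2 at 0.38 (adjusted p = 0.448) and C1qa at 0.45 (adjusted p = 0.499). The cholesterol synthesis list (0 of 17 called, median 0.18, adjusted p = 0.635), the mitochondrially encoded list (0 of 13 called, median 0.23, adjusted p = 0.0900) and the immediate-early list (3 of 21 higher and 1 lower, 5 and 2 adjusted over the list alone, median -0.11 while camera's direction was up, adjusted p = 0.969) did not pass even the preset test.

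For P301S;ATTAC versus C57BL/6;ATTAC, edgeR called 474 higher and 71 lower of 12223 genes (545), 2099 had an unadjusted p under 0.05, and DESeq2 called 335 higher and 10 lower. Of the 545, 537 had the same sign in both sexes and 14 had no control UMI. Without the low-Malat1 droplets 473 were called, 452 of them shared. Of the marker lists of cell types, border-associated macrophage markers alone passed the preset test (1 of 7 higher, Ms4a7, 3 adjusted over the list alone, median 1.01, adjusted p = 0.761 with an estimated correlation). The number of called genes was 0 from the compared groups alone, where sex was also left out, and 3 without the sex covariate over all 6 libraries. It was 142 without the male of P301S;ATTAC, 88 without the male control, 976 without the female control, and 924 and 873 without the female and the male of P301S. Over all cells, in place of microglia-like ones, it was 1 and the MHC class II genes H2-Aa, H2-Ab1 and H2-Eb1 turned to -0.44, -0.35 and -0.67, these genes being also among those that lead the border-associated macrophage-like cluster.

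**Figure D2:**
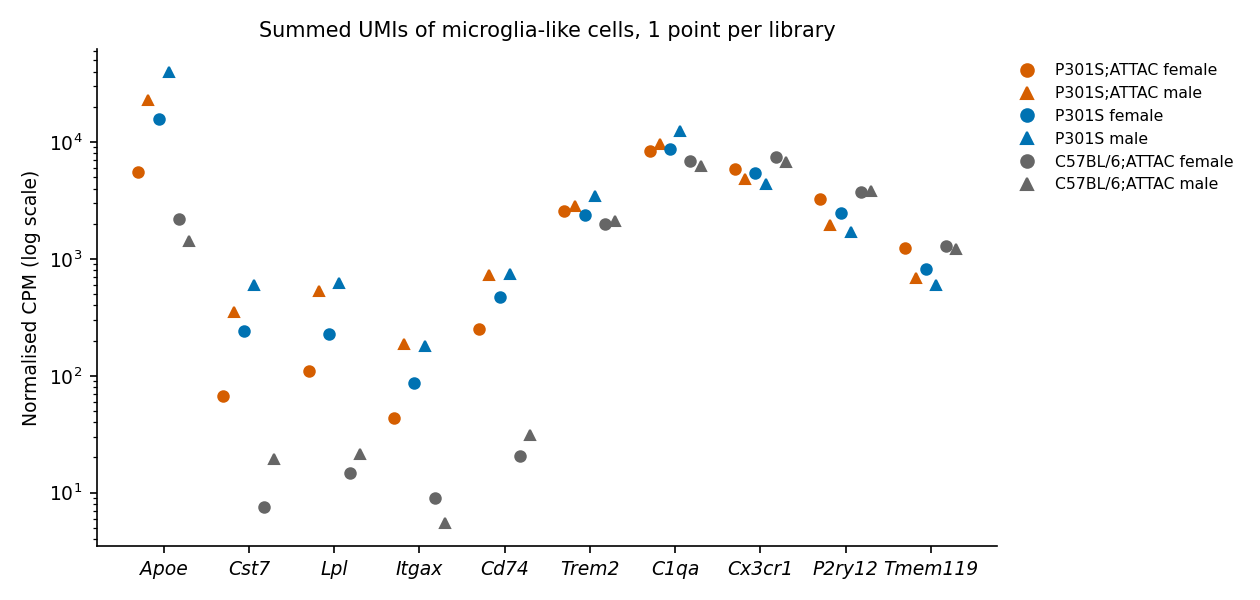
Normalised CPM on a log axis of 10 microglial genes in microglia-like cells, 1 point per library, coloured by genotype. Cst7 lies at 67.4, 349, 240 and 599 CPM in the P301S libraries and at 7.47 and 19.4 CPM in the controls.

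P301S mice without ATTAC and control mice differ by both labels, and the comparison uses the same control libraries as the preceding one. Here too disease-associated genes rose (n = 2 libraries per group), with Cst7 at 240 and 599 CPM against 7.47 and 19.4 (5.07 ± 0.25, adjusted p = 4.59e-10) and Apoe at 15742 and 39910 CPM against 2178 and 1412 (3.65 ± 0.52, adjusted p = 9.32e-05). Lpl rose by 4.54 ± 0.28, Lgals3 by 5.68 ± 0.31, Itgax by 4.41 ± 0.37 and the NADPH oxidase subunit Cybb by 4.66 ± 0.26. Spp1 had 19151 UMIs against 3, a ratio of 3475 (counting interval 1189 to 16853). Some homeostatic genes fell, though most of that list was not called. P2ry12 fell by 0.90 ± 0.25 (adjusted p = 0.0203) and Tmem119 by 0.85 ± 0.21 (adjusted p = 0.00839). P2ry13 fell by 0.89 ± 0.19 and the transcription factor Sall1 by 0.68 ± 0.16 on the log2 scale. The immediate-early genes Fosb fell by 2.70 ± 0.29, and Fos (chromosome 12, 85473890 to 85477273, plus strand) fell by 2.18 ± 0.25, at 3.53 and 5.82 CPM against 24.7 and 20.5. Other falling genes were Hist1h1e, which fell by 1.37 ± 0.16, and Hist1h1d, which fell by 1.65 ± 0.20, both linker histone genes.

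By list, 26 of 27 disease-associated genes rose (26 adjusted over the list alone, median 2.60, adjusted p = 0.111 with an estimated correlation), 22 of 24 interferon genes (23 adjusted over the list alone, median 1.48, adjusted p = 0.111 with an estimated correlation) and 6 of 7 MHC class II genes (7 adjusted over the list alone, median 4.15, adjusted p = 0.0997 with an estimated correlation). The interferon-induced Ifitm3 rose by 3.12 ± 0.19, Ifi27l2a by 3.58 ± 0.29, Cd74 by 4.59 ± 0.24 and H2-Aa by 5.10 ± 0.30. The MHC class II median was 2.19 without the disease-associated clusters and 0.29 in cluster 0 alone. Per cell and without thinning that list took a median of 0.0319 and 0.0488% of UMIs against 0.0169 and 0.0213% in controls (exact p = 0.2 over both P301S groups), and a 90th percentile of 0.188 and 0.306% against 0.0470 and 0.0565%. In the MHC class I list 9 of 12 rose (10 adjusted over the list alone, median 0.92, adjusted p = 0.107 with an estimated correlation), with H2-Q7 at 2.55 ± 0.20, and in the chemokine list 12 of 17 rose (13 adjusted over the list alone, median 1.64, adjusted p = 0.0997 with an estimated correlation), with Ccl3 at 3.39 ± 0.34 and Ccl2 at 2.28 ± 0.25. Fry, which does not compare a list with other genes, called the MHC class II (adjusted p = 0.0446), MHC class I (0.0341) and chemokine (0.0446) lists. Lipid-handling genes rose in 13 of 16 cases (14 higher and 1 lower adjusted over the list alone, median 1.98, adjusted p = 0.121 with an estimated correlation), including Fabp3 by 3.83 ± 0.32 and cholesterol 25-hydroxylase, Ch25h, by 4.12 ± 0.34. In the complement list 4 of 10 rose (5 adjusted over the list alone, median 0.62, adjusted p = 0.208 with an estimated correlation), C4b by 3.24 ± 0.28 and C3 by 4.89 ± 0.54, and C2 with 52 UMIs against 3 at a ratio of 9.44 (counting interval 3.06 to 47.2).

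In the senescence list 5 of 15 genes rose (6 adjusted over the list alone, median 0.25, adjusted p = 0.178 with an estimated correlation), namely Plaur by 2.22 ± 0.23, Glb1 by 1.01 ± 0.17, Cdkn2a by 2.83 ± 0.56 (15 and 87 UMIs against 1 and 7, adjusted p = 0.00157), Cdkn1a by 0.84 ± 0.19 and 1 more. Secretory phenotype genes rose in 17 of 26 cases and fell in 2 (17 and 2 adjusted over the list alone, median 1.29, adjusted p = 0.111 with an estimated correlation). Glycolysis (8 of 12 higher, 9 adjusted over the list alone, median 0.97) and oxidative phosphorylation (15 of 18 higher, 16 adjusted over the list alone, median 0.68) had adjusted p = 0.215 with an estimated correlation, as did lysosome genes (14 of 24 higher, 16 adjusted over the list alone, median 0.61) and mitochondrially encoded genes (8 of 13 higher, 10 adjusted over the list alone, median 0.70). Pgk1, an enzyme of glycolysis, rose by 1.32 ± 0.17, Cd63 of the lysosomal membrane by 1.82 ± 0.22 and mt-Nd1 by 0.76 ± 0.23. Cell-cycle genes rose in 7 of 13 cases (7 adjusted over the list alone, median 0.49, adjusted p = 0.146 with an estimated correlation). Homeostatic genes fell in 6 of 18 cases (7 adjusted over the list alone, median -0.47, adjusted p = 0.215 with an estimated correlation). Immediate-early genes, which tissue dissociation can induce, fell in 8 and rose in 4 of 21 cases (10 and 6 adjusted over the list alone, median -0.30, adjusted p = 0.215 with an estimated correlation). No cholesterol synthesis gene was called (median 0.19, preset adjusted p = 0.527).

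For P301S versus C57BL/6;ATTAC, edgeR called 1311 genes higher and 525 lower (1836 of 12223), 3400 had an unadjusted p under 0.05, and DESeq2 called 852 higher and 212 lower. Of the 1836, 1833 had the same sign in both sexes and 16 had no control UMI. Without the low-Malat1 droplets 1592 were called, 1566 of them shared. Border-associated macrophage markers (3 of 7 higher and 1 lower, 4 and 1 adjusted over the list alone, median 1.23) and microglial markers (5 of 16 lower, median -0.39) passed the preset test, each with adjusted p = 0.848 with an estimated correlation. Without the male control library 430 genes were called, without the male P301S library 881, and over all cells 5.

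In both P301S groups versus C57BL/6;ATTAC, averaged (4 libraries against 2), 1179 genes rose and 483 fell (1662 of 12223, 3248 at an unadjusted p under 0.05, and 770 higher and 152 lower by DESeq2). Cst7 was higher by 4.45 ± 0.24, Lpl by 4.25 ± 0.27, Lgals3 by 5.15 ± 0.30 and Cd74 by 4.37 ± 0.23 (adjusted p = 1.03e-09), and Spp1 had a ratio of 2876 (counting interval 984 to 13947). Cdkn2a rose by 2.29 ± 0.54 (adjusted p = 0.00728), Cdkn1a by 0.90 ± 0.18 and Apoe by 3.11 ± 0.49. P2ry12 and Tmem119 fell by 0.74 ± 0.21 and 0.64 ± 0.18, Jun by 0.83 and the linker histone gene Hist1h1c by 0.88 on the log2 scale. Of the disease-associated genes, 25 of 27 rose (26 adjusted over the list alone, median 2.32, adjusted p = 0.122 with an estimated correlation), and of the homeostatic genes 4 of 18 fell (5 adjusted over the list alone, median -0.36, adjusted p = 0.232 with an estimated correlation). The preset camera test called 16 of the 17 lists and camera with an estimated correlation called 0. Without the low-Malat1 droplets 1459 genes were called, 1433 of them shared. Without the male control library 269 were called, and over all cells 1.

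**Figure D3:**
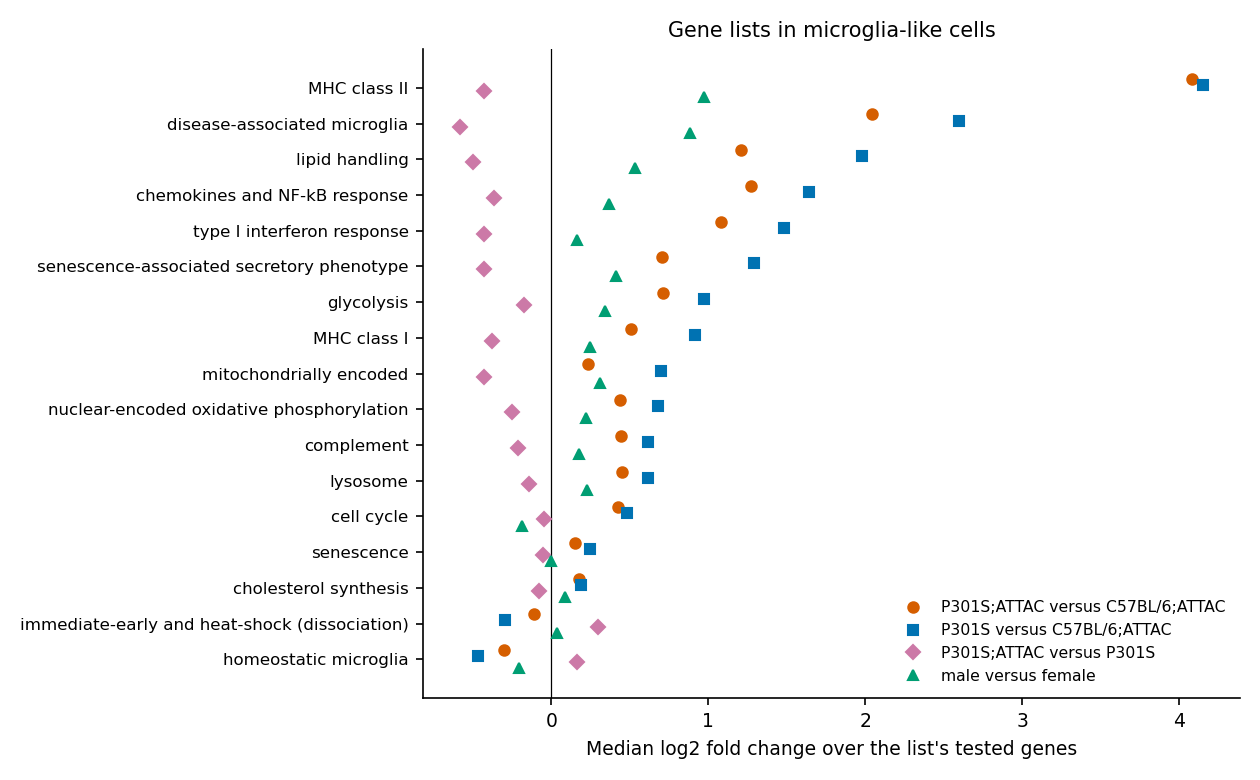
Median log2 difference of each of the 17 gene lists in 4 comparisons of microglia-like cells. The MHC class II list (4.08 and 4.15) and the disease-associated list (2.05 and 2.60) lie farthest above 0 in the comparisons of each P301S group with controls.

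P301S mice with and without ATTAC differ by the ATTAC label on the same tau background, so the comparison asks what ATTAC changes there. The libraries labelled P301S;ATTAC held 0 INKATTAC UMIs and those labelled P301S held 5 and 2, and no treatment is stated. By label, parts of the P301S response were lower with ATTAC (n = 2 libraries per group). Cst7 fell by 1.25 ± 0.20 (67.4 and 349 CPM against 240 and 599, adjusted p = 0.0125), Fabp5 by 1.25 ± 0.20, Spp1 by 1.69 ± 0.33 (adjusted p = 0.0347), and the MHC class I gene H2-Q7 by 1.34 ± 0.19 (adjusted p = 0.00557) on the log2 scale. The complement gene C4b fell to 4.61 and 10.9 CPM against 21.6 and 24.7 (adjusted p = 0.0124). The apolipoprotein genes Apoc1 and Apoc4 fell by 1.47 ± 0.25 and 1.58 ± 0.28. Fos and Fosb were higher with ATTAC, by 2.02 ± 0.25 (24.5 and 17.1 CPM against 3.53 and 5.82, with controls at 24.7 and 20.5, adjusted p = 0.00208) and 1.70 ± 0.31, as was Hist1h1d by 1.004 ± 0.20.

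All 27 disease-associated genes had a negative fold in that comparison, 4 were called lower (14 adjusted over the list alone), and the median was -0.58 (adjusted p = 0.168 with an estimated correlation). In cluster 0 alone the list's median was -0.06 with 0 genes called, and Lpl and Itgax turned to 0.36 and 0.42. Clusters 2 and 3 were the disease-associated clusters. Cluster 2 met that rule through Cd9, Timp2 and Ctsb, at 1.70, 1.56 and 1.52 times their level in other cells. At Leiden resolution 1 a cluster led by Lag3 and Cd9 did not meet it. Clusters 2 and 3 held smaller shares with the ATTAC label in each sex (6.17 and 18.9% against 13.1 and 24.97% in cluster 2, 4.97 and 19.4% against 12.7 and 24.6% in cluster 3). Without these clusters the list's median was -0.48 and 6 genes were called lower. Of the interferon genes 2 of 24 fell (12 adjusted over the list alone, median -0.43, adjusted p = 0.185 with an estimated correlation), Ifitm3 by 0.87 ± 0.16 and Cxcl10 by 1.63 ± 0.33. In the MHC class I list 1 of 12 fell (4 adjusted over the list alone, median -0.38, adjusted p = 0.119 with an estimated correlation), and fry called that list (adjusted p = 0.0115). In the MHC class II list 0 of 7 were called (4 lower adjusted over the list alone, median -0.43, adjusted p = 0.168 with an estimated correlation). Chemokine genes fell in 1 of 17 cases, Ccl5 by 1.70 ± 0.34 (3 adjusted over the list alone, median -0.37, adjusted p = 0.119 with an estimated correlation), secretory phenotype genes in 3 of 26 (6 adjusted over the list alone, median -0.43, adjusted p = 0.119 with an estimated correlation), lipid genes in 1 of 16 (5 adjusted over the list alone, median -0.50, adjusted p = 0.168 with an estimated correlation) and complement genes in 1 of 10 (1 adjusted over the list alone, median -0.21, adjusted p = 0.185 with an estimated correlation). Immediate-early genes rose in 2 of 21 cases (7 adjusted over the list alone, median 0.29, adjusted p = 0.119 with an estimated correlation).

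No gene was called over all genes in the homeostatic list (median 0.17, adjusted p = 0.304 with an estimated correlation), lysosome list (median -0.14, 0.478), glycolysis list (median -0.18, 0.478), oxidative phosphorylation list (median -0.25, 0.332) and mitochondrially encoded list (median -0.43, 0.185), which all passed the preset test. The senescence list (median -0.05, preset adjusted p = 0.0935), the cell-cycle list (median -0.04, 0.351) and the cholesterol synthesis list (median -0.08, 0.701) did not pass it. Panel genes that missed the threshold were Apoe at -1.07 ± 0.47 (adjusted p = 0.828), Cdkn2a at -1.07 ± 0.44 (adjusted p = 0.797), Lpl at -0.57 (adjusted p = 0.785), Cd74 at -0.43 (adjusted p = 0.852) and Tmem119 at 0.42 (adjusted p = 0.877). Of the astrocyte markers, 1 of 9 fell with the ATTAC label (Gfap, by 1.24 ± 0.23, and 3 adjusted over the list alone, median -0.35, adjusted p = 0.543 with an estimated correlation). Their summed share of UMIs was 0.0457% with ATTAC against 0.0411% without it in females, and 0.0328 against 0.0348% in males. Neutrophil markers had a median of 0.63 (0 of 6 called, 2 higher adjusted over the list alone, adjusted p = 0.449 with an estimated correlation). The preset test also called microglial markers (0 of 16 called, 0 adjusted over the list alone, median 0.14, adjusted p = 0.543 with an estimated correlation) and border-associated macrophage markers (0 of 7 called, 2 lower adjusted over the list alone, median 0.11 while camera's direction was down, adjusted p = 0.449 with an estimated correlation). It called the T cell and the choroid plexus or ependymal cell markers on 1 tested gene each (0.59 and 0.53, each higher adjusted over the list alone, with adjusted p = 0.449 with an estimated correlation).

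For P301S;ATTAC versus P301S, 7 genes rose and 20 fell (27 of 12223), 686 had an unadjusted p under 0.05, and DESeq2 called 5 higher and 10 lower. All 27 had the same sign in both sexes. The number moved with each library left out, to 49 and 149 without the female and the male of P301S;ATTAC, 50 and 67 without those of P301S, and 146 and 149 without those of C57BL/6;ATTAC. Without the low-Malat1 droplets 47 genes were called, 25 of them shared, over all cells 0, and without the sex covariate 0.

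Male and female libraries were compared with genotype as the covariate (n = 3 libraries per sex). Beyond the sex chromosomes, 13 of 27 disease-associated and 5 of 7 MHC class II genes were called higher in males, while neither list passed with an estimated correlation. In the controls Apoe (2178 CPM in the female and 1412 in the male) and the per-cell median of the disease-associated list (1.87 and 1.73% of UMIs) went the other way. Cst7 rose by 1.73 ± 0.18 (adjusted p = 1.82e-05), Lpl by 1.57 ± 0.21, Gpnmb by 2.80 ± 0.33, Ch25h by 2.06 ± 0.25, Mmp12 by 2.42 ± 0.31 and Cd74 by 0.97 ± 0.17. The calprotectin genes of neutrophils were higher in each male library, S100a8 (chromosome 3, 90668978 to 90670035, plus strand) at 21.6, 17.1 and 15.5 CPM against 1.44, 1.48 and 1.49 (3.57 ± 0.25, adjusted p = 3.18e-08) and S100a9 at 37.6, 22.96 and 22.6 CPM against 3.46, 2.27 and 2.24 (3.36 ± 0.20, adjusted p = 2.87e-09). Eif2s3y, Ddx3y and Uty were at least 397-, 369- and 199-fold higher in males, whose female counterparts had 0 UMIs, and Xist fell by 12.79 ± 0.31 on the log2 scale. Kdm6a, an X-linked demethylase, fell by 0.86 ± 0.12. Gnb4 fell by 5.33 ± 0.43, with high values in 2 of 3 female libraries (0.576, 14.0 and 19.7 CPM).

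Of the disease-associated genes, 13 of 27 were higher in males (23 adjusted over the list alone, median 0.89, adjusted p = 0.248 with an estimated correlation), of the MHC class II genes 5 of 7 (6 adjusted over the list alone, median 0.97, adjusted p = 0.232 with an estimated correlation) and of the lipid genes 5 of 16 (7 adjusted over the list alone, median 0.53, adjusted p = 0.248 with an estimated correlation). Secretory phenotype genes were higher in 4 of 26 cases (11 higher and 1 lower adjusted over the list alone, median 0.41) and chemokine genes in 2 of 17 (5 adjusted over the list alone, median 0.37), each with adjusted p = 0.243 with an estimated correlation. The chemokine gene Cxcl2 had 114 UMIs in males and 3 in females, a ratio of 15.6 (counting interval 5.195 to 76.6). Crybb1 was the 1 of 18 homeostatic genes that fell (1 adjusted over the list alone, list median -0.21, adjusted p = 0.452 with an estimated correlation). Preset calls without an estimated-correlation call were also made for the MHC class I (0 of 12 called, 3 adjusted over the list alone, median 0.25, 0.243), interferon (1 of 24, 3 higher and 1 lower adjusted over the list alone, median 0.16, 0.525), lysosome (0 of 24, 1 adjusted over the list alone, median 0.22, 0.525), glycolysis (0 of 12, 5 adjusted over the list alone, median 0.34, 0.457), oxidative phosphorylation (0 of 18, 0 adjusted over the list alone, median 0.22, 0.525) and mitochondrially encoded (1 of 13, 3 adjusted over the list alone, median 0.31, 0.376) lists, each last value being the adjusted p with an estimated correlation. The senescence, cell-cycle, cholesterol synthesis, complement and immediate-early lists had preset adjusted p of 0.561, 0.734, 0.424, 0.353 and 0.0712.

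For male versus female, 119 genes rose and 53 fell in males (172 of 12223), 1321 had an unadjusted p under 0.05, and DESeq2 called 48 higher and 22 lower. Of the 172, 157 had the same sign in all 3 genotypes. All 5 tested genes of the Y chromosome were among them (Fisher's exact test, adjusted p = 1.09e-08 over chromosomes), which a comparison of the sexes entails. On the X chromosome 11 of 365 tested genes were called (Fisher's exact test, adjusted p = 0.204). Neutrophil markers were higher in 5 of 6 cases (5 adjusted over the list alone, median 3.47, preset adjusted p = 1.44e-28, adjusted p = 0.217 with an estimated correlation), and border-associated macrophage markers in 3 of 7 (5 higher and 1 lower adjusted over the list alone, median 1.57, adjusted p = 0.217 with an estimated correlation). The preset test also called microglial markers (0 of 16 called, 0 adjusted over the list alone, median -0.18, adjusted p = 0.606 with an estimated correlation), 1 choroid plexus or ependymal cell marker (higher, 1.25, adjusted p = 0.217 with an estimated correlation) and 1 T cell marker (lower, -0.71, adjusted p = 0.338 with an estimated correlation). Neutrophil-like cells averaged 1.004% of cells in male and 0.113% in female libraries (21, 30 and 15 cells against 1, 3 and 0, exact permutation p = 0.1, the smallest possible). Without the female or the male control library 543 and 550 genes were called, over all cells 12, without the genotype covariate 8, and without the low-Malat1 droplets 221.

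Whether the response to P301S differs by sex was tested as an interaction (P301S effect in males versus females). EdgeR called 0 of 12806 genes, with 488 at an unadjusted p under 0.05 and a smallest adjusted p of 0.129, and DESeq2 called 3 higher and 2 lower. Leaving out the female or the male of P301S;ATTAC gave 14 and 55 calls, and of P301S 111 and 26. Without the low-Malat1 droplets 0 were called. The preset camera test called 9 lists, each with adjusted p = 0.704 with an estimated correlation. The disease-associated list had a larger P301S effect in males (median 0.80) and the interferon list a smaller one (median -0.63).

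Per cell, thinned to 1500 UMIs (331, 1037, 771, 1743, 322 and 856 cells), disease-associated genes took a median of 2.33, 4.53, 3.27, 6.20, 1.87 and 1.73% of UMIs and a 90th percentile of 5, 10.3, 9.47, 13.3, 3.06 and 2.60%. Both the middle and the upper end of the distribution were higher in every P301S library than in the controls. The mean of medians was 4.08% in P301S and 1.80% in control libraries (exact permutation p = 0.133), and that of 90th percentiles 9.52 and 2.83% (exact p = 0.133). Without 5 abundant members (Apoe, Fth1, Lyz2, Ctsb and Ctsd) the means of medians were 1.32 and 0.767%, a difference of 0.55 in place of 2.28 points (exact p = 0.133). With the low-Malat1 droplets left out, and without thinning, the disease-associated medians were 2.22, 3.67, 2.81, 5.14, 1.84 and 1.71%. Homeostatic genes took a median of 3.93, 2.93, 3.07, 2.27, 4.50 and 4.20%, with means of 3.05 and 4.35% (exact p = 0.133). P301S mice with ATTAC had a mean median of 3.43% and those without it 4.73% for the disease-associated genes (exact p = 0.667). The test ignores sex, and within each sex the median was lower with ATTAC (2.33 against 3.27% in females, 4.53 against 6.20% in males). Males averaged 4.16% and females 2.49% (exact p = 0.4). In the cells outside clusters 2 and 3, the median log2 difference of the list between P301S mice without ATTAC and controls was 1.51, and in cluster 0 alone 0.66, against 2.60 in all microglia-like cells.

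**Figure D4:**
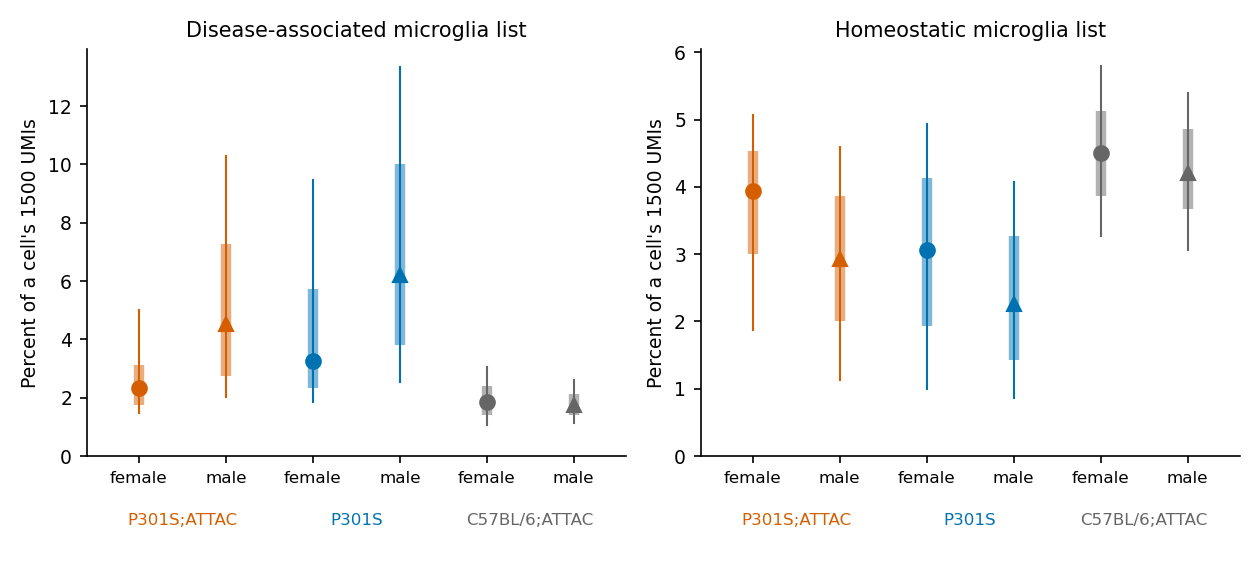
Percent of each cell's UMIs in the disease-associated and homeostatic lists, for microglia-like cells thinned to 1500 UMIs. Markers are library medians, thick lines the 25th to 75th and thin lines the 10th to 90th percentiles, and the disease-associated medians run from 1.73 to 1.87% in controls and from 2.33 to 6.20% in P301S libraries.

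Cdkn2a, which has p16 as a product (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653, minus strand), was rare. INK-ATTAC uses the promoter of p16. Counts per gene do not tell the transcripts of Cdkn2a apart. Without thinning, 3, 26, 9, 54, 1 and 7 microglia-like cells had a UMI, or 0.880, 2.41, 1.13, 2.97, 0.311 and 0.814%. Thinned to 1500 UMIs, 0, 4, 3, 10, 0 and 1 cells had one. By cluster and without thinning, the shares in the 4 P301S libraries were 0 of 37 cells (up to 8.11%), 3.13, 1.61 and 4.53% in cluster 3, 0 of 22 (up to 13.6%), 4.41, 3.26 and 4.67% in cluster 7, 2.17, 2.34, 1.04 and 2.03% in cluster 2 and 0.847, 1.27, 0.306 and 0.417% in cluster 0. Over all libraries, 0 of 164 astrocyte-like and 0 of 151 choroid plexus or ependymal cell-like cells had a UMI (up to 1.83 and 1.99%). Cluster 3 cells had a median depth of 4866.5 UMIs, cluster 0 cells 9705, astrocyte-like cells 6177.5 and choroid plexus cells 23445.

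**Figure D5:**
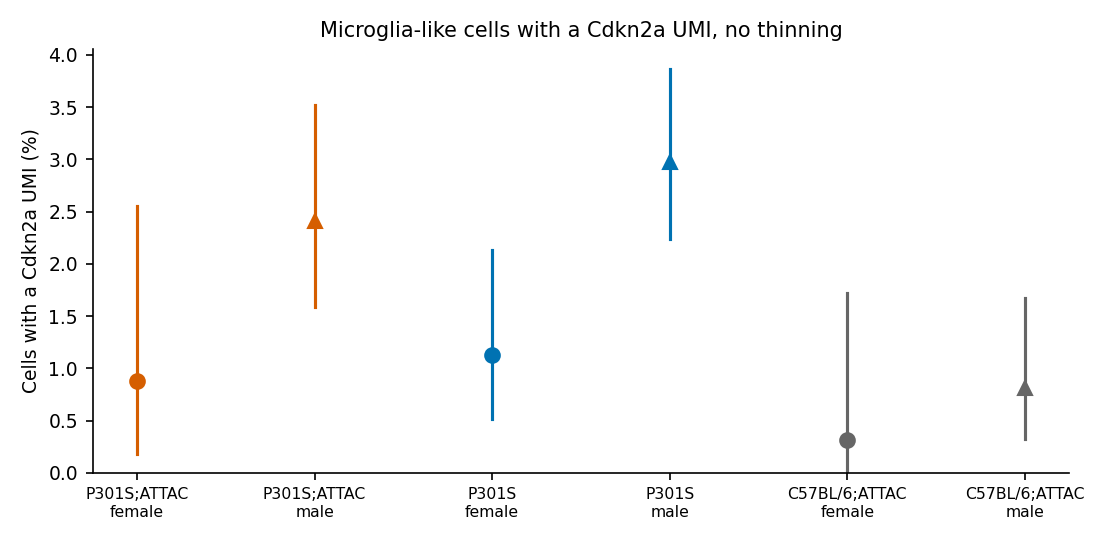
Percent of microglia-like cells with a Cdkn2a UMI in each library, without thinning, with exact 95% intervals. The share is 0.311 and 0.814% in the controls and 0.880 to 2.97% in the P301S libraries.

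Cells with a Cdkn2a UMI were compared with the other microglia-like cells of their library, to ask which programme accompanies this transcript. In the 4 libraries with at least 5 such cells, the disease-associated list was 1.73 ± 1.48 points (SD) higher in them, in 3 of 4 libraries (2.14, 1.69, 3.33 and -0.234 points), and the exact sign-flip test gave p = 0.25 where 0.125 is the smallest possible. The homeostatic list was -0.471 ± 0.0818 points (SD), lower in all 4 (exact p = 0.125). Positive cells were deeper in 3 of 4 libraries (median 14670.5 against 9330 UMIs in the male P301S library) and shallower in the male control (8862 against 9299 UMIs). Against the negative cells nearest in depth the disease-associated difference was 1.57 ± 1.63 points (SD, exact p = 0.25) and the homeostatic one -0.548 ± 0.172 (exact p = 0.125), but in the female P301S library these cells were still shallower (median 14586.5 against 19409 UMIs). Thinned, a single library had enough cells, with 4.04 points, so the planned test had no replicates. For Cdkn1a, thinned, the homeostatic list differed by -0.721 ± 0.284 points (SD), lower in 6 of 6 libraries (exact p = 0.0312, the smallest possible), and by -0.347 points at 1000 UMIs (5 libraries, exact p = 0.125, where 0.0625 is the smallest possible). Without thinning the difference was -0.118 ± 0.0410 points, and against the negative cells nearest in depth -0.202 ± 0.0643 points (SD), lower in 6 of 6 libraries in each case (exact p = 0.0312). Those negative cells were still shallower in 5 of 6 libraries (median 10680 against 12903 UMIs in the female of P301S;ATTAC), so depth was narrowed and not matched. The disease-associated list differed by 0.127 ± 0.404 points (SD) thinned (exact p = 0.469) and by 0.0929 ± 0.173 without thinning (exact p = 0.375). Against the negative cells nearest in depth it was 0.123 ± 0.115 points higher, in 5 of 6 libraries (exact p = 0.0625).

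Gene by gene, cells with a Cdkn2a UMI had higher Fabp5 (1.76 ± 0.13, adjusted p = 2.1e-37), Ms4a6c (1.07 ± 0.16), the lipid-droplet gene Plin2 (1.01 ± 0.21), the actin-capping gene Capg (0.84 ± 0.16), Apoe (0.57 ± 0.15, adjusted p = 0.0250) and the receptor Axl (0.54 ± 0.14), in 4 of 4 libraries each. Lower in 4 of 4 were Jun, which fell by 0.92 ± 0.14 (adjusted p = 2.71e-08), P2ry12, which fell by 0.56 ± 0.12, Tmem119, which fell by 0.52 ± 0.12, and Ccl5, which fell by 1.38 ± 0.24. The same sign in every library was a condition of the naming rule, but not for panel genes. Lpl (0.62 ± 0.13), Itgax (0.54 ± 0.14) and Cdkn1a (0.99 ± 0.26) were called higher, with that sign in 3 of 4 libraries each. Cst7 (0.48 ± 0.13) was called with that sign in 2 of 4. Cx3cr1, Ifit3, Il1b, Cd74, C1qa and Trem2 were not called, though Cx3cr1 and Il1b were lower in 4 of 4 libraries. EdgeR called 88 genes higher and 25 lower (113 of 11354), 915 had an unadjusted p under 0.05, and DESeq2 called 6. Random cells drawn from those nearest in UMIs gave 5 to 32 calls in 20 draws (median 15.5). The fit had 3 residual and infinite prior degrees of freedom. Each gene's own spread thus had no weight in its edgeR p value. Without the male of P301S;ATTAC 35 genes were called, without the male of P301S 16 and without the male of C57BL/6;ATTAC 180.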

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

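The tests of free RNA and of the disease-associated clusters below were chosen only after the result was seen, while the count over splits of the libraries was planned.

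INKATTAC, whose transcript no comparison uses, gave 5 UMIs in the female and 2 in the male library labelled P301S, whose label names no ATTAC, where the libraries labelled P301S;ATTAC gave 0. The control libraries, labelled ATTAC, had 3 and 4 UMIs.

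The effect of P301S differed between the sexes by the preset camera test of the interaction for 9 lists, though none with an estimated correlation (adjusted p = 0.704). The median log2 difference, males minus females, was 0.80 for disease-associated, 0.59 for lipid-handling, 0.59 for glycolysis, 0.40 for lysosome, 0.40 for oxidative phosphorylation and 0.37 for mitochondrially encoded genes. It was 0.0259 for immediate-early, -0.25 for homeostatic and -0.63 for interferon genes. The percent of UMIs in the disease-associated list per cell (library medians) was higher in the male by 2.20 points in P301S mice with ATTAC and by 2.93 points in those without it, against -0.133 points in controls. With 1 library per sex and genotype this last difference was not tested.

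Disease-associated genes were higher in male libraries, 13 of 27 by call, and 172 genes were called between the sexes. Free RNA is argued against as the cause, since the male minus female difference of the 13 called members in choroid plexus or ependymal cell-like cells was a median of 0.0232 of that in microglia-like cells. A larger share of cells from the disease-associated clusters may add to the pattern. The list's median log2 difference was 0.65 without those clusters and 0.89 with them, so they did not hold all of it. Genes of this list help define those clusters, so a wider shift in cell composition cannot be told apart. Of 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave as many as 172 genes and the highest other gave 3, and 10 splits are too few for a share under 0.05. Genotype stayed in each fit, so splits with both libraries of a genotype in 1 arm drew on the libraries of 1 genotype and had less power. The other splits that parted every genotype gave 3, 0 and 0, with the sex difference left in their spread. No conclusion is drawn from the count. Sex itself, or another difference between the mice or their handling, stays open and untested.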

How the results depend on the processing

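Cluster 0 alone, the low-UMI clusters, the removal of low-Malat1 droplets and negative cells nearest in depth were chosen only after the results were seen. So was leaving out a library for class shares and per-cell list values. For gene lists, so were all cells, no disease-associated clusters and libraries thinned to the smallest. The other alternatives were chosen before. No paired analysis was possible because the labels give no replicate numbers and name no shared animal, litter or day. The numbers used here follow sample order, female then male, so a replicate block would be the sex covariate already in the fit. Called genes that the rule named or that led a list, 274 counted per comparison, had 5307 values under all alternatives. Of these, 4210 kept direction and call, 1087 kept direction alone and 10 reversed. Most of these genes were picked for a small p and the same sign in both sexes. The counts therefore do not cover all called genes. Of 1188 values of called lists 976 kept both, 207 kept direction alone and 5 reversed. Of 658 values of panel genes not called 605 stayed so, 35 passed the threshold and 18 changed sign. Except where the construction shows it (fewer cells, genes or libraries), the cause was not tested. At 1500 UMIs too few cells kept a Cdkn2a UMI, so the thinned comparison by Cdkn2a UMI could not be fitted. With 200 genes and 20% mitochondrial UMIs no T cell-like cluster formed and that share has no value. Fits from the compared groups alone also left out sex.

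Called genes in P301S;ATTAC versus C57BL/6;ATTAC, 545 as reported, were 915 with no low-count filter, 345 by DESeq2, 3 without the covariate, 0 from the compared groups alone, 1 over all cells, 297 with 200 genes and 20% mitochondrial UMIs, 122 without the disease-associated clusters and 49 in cluster 0 alone. In P301S versus C57BL/6;ATTAC (1836) they were 1064 by DESeq2, 675 without the covariate, 1158 from the groups alone, 5 over all cells, 514 without those clusters and 77 in cluster 0. In P301S;ATTAC versus P301S (27) they were 131 unfiltered, 15 by DESeq2, 0 without the covariate, 1 from the groups alone, 0 over all cells, 5 with 200 genes and 20%, 13 with doublets kept, 67 without those clusters, 9 in cluster 0 and 47 without low-Malat1 droplets. For both P301S groups versus C57BL/6;ATTAC (1662) they were 922 by DESeq2, 249 without the covariate, 1 over all cells, 446 without those clusters and 103 in cluster 0. For male versus female (172) they were 408 unfiltered, 70 by DESeq2, 8 without the covariate, 12 over all cells, 102 with 200 genes and 20% and 67 in cluster 0. For the interaction (0, with 488 at an unadjusted p under 0.05) they were 39 unfiltered, 5 by DESeq2, 1 with 200 genes and 20%, 1 at resolution 1, 3 thinned to the smallest library, 1 without those clusters and 3 in cluster 0. Called lists were 0 in each of the 6 comparisons with an estimated correlation, and 0, 3, 1, 0, 0 and 0 with fry. Cdkn2a-positive versus Cdkn2a-negative cells gave 6 genes by DESeq2.

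Leaving out 1 library at a time, the counts ran from 88 to 976 in P301S;ATTAC versus C57BL/6;ATTAC, 430 to 2129 in P301S versus C57BL/6;ATTAC, 49 to 149 in P301S;ATTAC versus P301S, 269 to 2267 in both P301S groups versus C57BL/6;ATTAC, 148 to 550 in male versus female and 14 to 111 in the interaction (from which control libraries cannot be left out), from 9 to 14 for the lists of P301S;ATTAC versus P301S, and from 16 to 180 for Cdkn2a status. Shares and per-cell medians are not adjusted for sex, and leaving out 1 library makes the sexes unequal between groups. Differences in shares for both P301S groups ran from -0.211 to 0.628 points (neutrophil-like), from -1.65 to 0.296 (border-associated macrophage-like) and from -1.60 to 0.438 (cell class shares, choroid plexus or ependymal cell-like, both P301S groups versus C57BL/6;ATTAC). For males they ran from -0.666 to 0.678 (border-associated macrophage-like, 0.122 with doublets kept) and from -0.00766 to 1.05 (cell class shares, choroid plexus or ependymal cell-like, male versus female). The disease-associated list per cell, median, P301S;ATTAC versus P301S, ran from -2.77 to 0.167. At 1000 UMIs the disease-associated list in Cdkn1a-positive cells was -0.186 and the homeostatic one -0.347.

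Log2 values that reversed were, over all cells in P301S;ATTAC versus C57BL/6;ATTAC, Ms4a7 -0.0158, H2-Aa -0.44, H2-Ab1 -0.35, H2-Eb1 -0.67 and Nr4a1 in P301S;ATTAC versus C57BL/6;ATTAC -0.0388, while H2-Eb1 in both P301S groups versus C57BL/6;ATTAC was -0.0304. In cluster 0 alone H2-Eb1 in P301S versus C57BL/6;ATTAC was -4.56e-05 and Ccl2 was -0.58. Between the 2 P301S groups cluster 0 alone gave Wfdc17 0.58, Lpl 0.36, Itgax 0.42, Trem2 in P301S;ATTAC versus P301S 0.0856, P2ry12 in P301S;ATTAC versus P301S -0.0538, Cx3cr1 in P301S;ATTAC versus P301S -0.0331, Cd74 in P301S;ATTAC versus P301S 0.0810 and C1qa 0.0182, Cdkn1a was -0.11 over all cells and -0.12 thinned, and Trem2 0.0244 without the disease-associated clusters. With a library left out, Itgax in P301S;ATTAC versus P301S ran from -1.25 to 0.25, Trem2 from -0.32 to 0.13, Ifit3 from -0.41 to 0.0277, Cdkn1a from -0.13 to 0.27, Il1b in P301S;ATTAC versus P301S from -0.95 to 0.0472 and C1qa from -0.45 to 0.0253 there. For male versus female Ifit3 was 0.38 without those clusters and 0.33 in cluster 0, and Itgax -0.24 in cluster 0. Lists that turned had camera p of 0.653 (MHC class II, P301S;ATTAC versus C57BL/6;ATTAC, all cells), 0.0379 (type I interferon response list in P301S effect in males versus females, without those clusters) and 0.0383 (oxidative phosphorylation in that interaction, all cells). With a library left out, camera p ran from 2.62e-05 to 0.964 for lysosome in P301S;ATTAC versus P301S and from 2.35e-07 to 0.706 for the immediate-early and heat-shock (dissociation) list in P301S effect in males versus females.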

Other observations

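The tests in this part were all chosen only after the results were seen.

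The share of cells with a human tau UMI was higher among astrocyte-like than microglia-like cells of each P301S library, at 9.09, 12.5, 9.52 and 9.09% against 1.17, 0.464, 1.38 and 0.551% without thinning. Thinned to 1500 UMIs, 1 of 16, 1 of 20, 2 of 18 and 0 of 17 astrocyte-like cells had one against 1 of 331, 0 of 1037, 0 of 771 and 0 of 1743 microglia-like cells, so the male P301S library without ATTAC no longer shows it. In the control libraries 0 of 27 and 0 of 48 astrocyte-like cells (up to 11.1 and 6.25%) and 0 of 322 and 0 of 860 microglia-like cells (up to 0.932 and 0.349%) had one. Over the 4 P301S libraries and without thinning, 10.1% of astrocyte-like cells (9 of 89) and 13.04% of choroid plexus or ependymal cell-like cells (12 of 92) had an hMAPTP301S UMI, against 0.744% of microglia-like cells (30 of 4031) and 0.806% of border-associated macrophage-like cells (2 of 248). Thinned to 1500 UMIs, the shares were 5.63% (4 of 71), 2.27% (2 of 88), 0.0258% (1 of 3882) and 0.467% (1 of 214), where the exact interval of border-associated macrophage-like cells (0.0118 to 2.58%) overlapped those of astrocyte-like (1.56 to 13.8%) and choroid plexus cells (0.276 to 7.97%).

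Interferon-induced genes led cluster 7, a small group of microglia-like cells. It held 2.95, 3.75, 6.30 and 3.61% of cells in the P301S libraries and 0.776 and 1.57% in the control libraries, and was described without a test. Without thinning, 27.3, 23.5, 17.4 and 26.2% of its cells in the P301S libraries had a Cdkn1a UMI, against 5.93, 9.81, 10.1 and 5% in cluster 0, 15.2, 16.96, 9.90 and 10.5% in cluster 2 and 16.2, 15.1, 13.4 and 10.8% in cluster 3. Thinned to 1500 UMIs, the shares were 16.7, 6.15, 3.45 and 10.1% in cluster 7 and 3.23, 3.48, 2.99 and 3.29% in cluster 3. In the male control the order did not hold without thinning, with 7.14% (2 of 28) in cluster 7, 13.8% in cluster 2 and 12.5% in cluster 3. Cluster 11 (88 cells) was led by Top2a, Mki67 and Prtn3, the last a granule gene of myeloid precursors found in 14.8% of its cells, and stayed unnamed.

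Neutrophil genes were higher in microglia-like cells of the male libraries, where S100a8 or S100a9 UMIs lay in 50.1, 28.6 and 33.3% of these cells, against 4.11, 3.64 and 3.73% in females. Doublets with neutrophils are argued against, since 2.34% of those UMIs lay in cells with 5 or more. Free RNA from neutrophils is a candidate explanation, since the 5 called markers had in astrocyte-like, border-associated macrophage-like and choroid plexus cells of male libraries a median of 0.799 of their CPM in microglia-like cells. Neutrophil-like cells averaged 1.004% of cells in male and 0.113% in female libraries (exact p = 0.1, the smallest possible). Whether that reflects the mice or how fully their blood was removed was not tested, and sex stays open.

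Low-Malat1 droplets were more frequent among microglia-like droplets of P301S libraries. They may be droplets without a nucleus, since Xist, Neat1 and Kcnq1ot1, RNAs kept in the nucleus, had a median of 0.00353 of their CPM in the other droplets, while Actb and C1qa had 1.24 and 1.12, though within the P301S libraries P2ry12 had 0.117 to 0.257 and Spp1 2.14 to 18.95. Among droplets of at least 5000 UMIs the shares were 1.39, 10.6, 6.23 and 10.3% in P301S and 0.647 and 0.248% in control libraries (means 7.12 and 0.448%, exact p = 0.133). The lowest P301S share exceeded the highest control share by 0.746 points with overlapping intervals, so lower depth cannot be told apart as a source of the difference. With the low-UMI clusters added, the P301S minus control difference was 11.3 points in place of 19.96, so the choice of clusters also stays open.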
